A study of Oryza sativa with 48 samples.

How the data were processed

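RNA was isolated with the Sigma Spectrum Plant Total RNA kit and made into TruSeq Stranded Total RNA libraries after Ribo-Zero Plant depletion, per the labels' protocols. Rice was grown at 30 °C; the labels give each group 3 replicates and do not say whether they were separate cultures, so p-values may measure a technical spread. Cufflinks, Bowtie2, TopHat2 and Cuffdiff, each listed as version 2.2.0, are named in the submitters' processing notes. The genome build, the annotation and the settings of these tools are not given in the sources used here.

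The 28 deposited tables each hold 2 groups and 60435 features. The group means are in FPKM, as deposited by the authors. The log2 ratio of the groups, the test statistic (a score without fixed range), the p-value and the q-value were computed by the authors per the file headers. Every q-value was recomputed from the deposited p-values of its table by Benjamini-Hochberg and differed by at most 1e-06. The smallest deposited p-value is 5e-05, which many features share. The tables were normalized separately: the level of a group differed between tables by a constant factor of up to 1.59 (24 h air), so levels are compared within a table only. Where 3 tables close a triangle, the log2 ratios added up with a median residual between -0.0044 and 0.0036.

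A gene was called at a deposited q of 0.05 or less among features with status OK, as fixed before the data were examined. The implied SE is the size of the log2 ratio divided by the test statistic. It is large for some genes with a small q. The deposited p does not come from a normal distribution, and this shows with an ordinary SE as well. SUS2 at 1 h had 0.30 ± 0.17 with a deposited Cuffdiff p of 0.00125, and PCNA at 3 h 0.34 ± 0.21 with 0.00515. A normal p would be larger for both. It would be smaller for EXPA8 at 24 h (-5.59 ± 1.37, deposited Cuffdiff p of 0.00265). A ± value below can therefore differ from the spread behind a call. The median shift of a table is the median log2 ratio over tested genes with FPKM of 1 or more in both groups. Calls on centred ratios subtract it and use a normal p from the implied SE, so that both change; calls with the normal p and no centring are given beside them. Of 60435 features 4206 carry no locus and 1197 merge several loci. Those without a locus hold from 39.1% (2 d air) to 62.5% (dry seed) of the summed FPKM of a group; they were tested with the rest, and calls without them were an alternative.

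There were 14 gene lists with 257 loci fixed before the data were examined. The reference table (assembly ASM3414082v1) was used for names only. It carries the symbol of 151 members at a matching position, within 1 Mb of the place its neighbours predict; 3 members were contradicted and dropped, 102 have no name there, 1 was not in the tables, and 253 were used, 25 of them in a merged feature. Called members of a list were set against other tested genes with Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg over 252 tests (14 lists, both directions, 9 tables). In 73 of these the adjusted p was 0.05 or less, 60 with more calls than other genes and 13 with fewer. A median was ranked among 10000 random lists matched on 10 classes of mean FPKM. Differences of a list between successive times were tested on centred ratios of its members by a two-sided sign-flip test, exact under 10 members and with 100000 permutations otherwise; members of a list are not independent replicates. cameraPR of limma 3.58.1 (R 4.3.3) with a preset correlation of 0.01 was an alternative; an estimated correlation needs values per library and was not run.

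The rule for named genes was fixed before the data were examined: up to 3 called members per list with the largest change and FPKM of 5 or more, the 4 highest and 4 lowest called genes with FPKM of 20 or more, and 10 genes always (2 members per list in the time course). The second part was run over list members whose symbol the reference carries, which is narrower than the rule as fixed, since names of other loci were not matched. Members without such a symbol stay in the counts and are not named, except EXPB12, which the rule names always. Genes with near-identical copies (glutelins, small heat shock proteins, RAB21, amylases) are uncertain, since reads can be split between copies.

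Alternatives were a q of 0.01, a change of 2-fold, an FPKM minimum of 1, adjustment over all tables, centring and a pseudocount of 1, fixed beforehand. A normal p without centring, features with a locus, checked members, lists without the 4 d air tables and centred calls for lists, reversal and agreement were added after seeing the data. The functions were tested on simulated data for the 12 h comparison with 20687 genes and 50 changed genes per size. With centring, 4 of 50 genes were recovered at a log2 change of 0.5, 27 at 1, 44 at 2 and 47 at 4, and 5 unchanged genes were called. The noise was normal with the implied SE, which the centred calls assume too, so few false calls were built in. Far fewer genes were changed than the 43.5% of features called at 12 h, and the deposited q was not simulated. Recovery in the data can therefore differ. Shared 4 d nitrogen libraries were simulated 100 times from the variances implied by 3 tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.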

Results

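The data describe the transcriptome of rice (*Oryza sativa* cv. Amaroo) during germination in culture medium bubbled with air or with nitrogen gas, which removes oxygen. There were 48 libraries in 16 groups of 3: dry seed, 7 times from 1 h to 4 d in air and in nitrogen, and coleoptiles kept for 3 d in nitrogen and then for 1 d in air. Embryos were sampled up to 24 h and whole coleoptiles, the sheath that emerges first from the rice seed, from 2 d on. The files hold 28 tables, each comparing 2 groups over 60435 features, with a mean FPKM (fragments per kilobase of transcript, scaled to the size of the library) per group. They carry no values per library, so the read depth is unknown and no spread between libraries could be computed; errors below are the standard errors (SE) implied by the authors' deposited ratio and test statistic. A gene was called at a deposited q of 0.05 or less, and all gene values below are those of the authors' deposited tables. Ratios are nitrogen over air unless stated.

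At 1 h, transcripts of endosperm storage proteins, the reserve proteins of the seed, were slightly higher in nitrogen. Of 11 tested members 6 were called higher and 0 lower (7 higher when adjusted over the list alone), with a median log2 ratio of 0.33 (adjusted p = 2.63e-07, Fisher's exact test). In the authors' deposited table GLUA3, a glutelin, went from 14.2 FPKM in air to 19.3 in nitrogen (log2 ratio 0.45 ± 0.17 SE). None of the 11 was called with a normal p on centred ratios, and the list did not pass with 2-fold or more. Among amylases, which break down starch, 2 of 4 members were called higher (adjusted p = 0.00892, Fisher's exact test), with AMY3E at 34.1 FPKM in air and 53.4 in nitrogen in the authors' deposited table. Of 25 heat shock protein genes 4 were called lower (adjusted p = 0.0348, Fisher's exact test), among them HSFB2C, a heat shock factor (log2 ratio -0.47 ± 0.18 in the authors' deposited table). The heat shock list did not pass with cameraPR, with 2-fold or more or with a background of FPKM of 1 or more, and none of its members was called with a normal p on centred ratios. ABA8OX1, an enzyme that degrades abscisic acid, was lower at -0.71 ± 0.17 in the authors' deposited table. The fermentation genes ADH1 (0.09 ± 0.16) and PDC1 (-0.06 ± 0.20) were not called in the authors' deposited table at this time. In all, 1215 of 24187 tested features were called, 399 higher and 816 lower in nitrogen. Higher calls made up 32.8% as deposited, 9.1% with a normal p from the implied SE, and 7.2% with that p on ratios centred on their median (shift 0.05). That share was 22.4% at a q of 0.01 or less, 5.6% with 2-fold or more, and 49.5% when adjusted over all tables together, which gave 2621 calls, 1298 higher and 1323 lower.

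At 3 h, embryo maturation transcripts were higher in nitrogen. Of 15 embryo maturation genes, which encode LEA proteins and oleosins of the dry seed, 12 were called higher and 2 lower (median log2 ratio 0.57, adjusted p = 2.96e-05, Fisher's exact test). LEA3 stood at 427 FPKM in air and 836 in nitrogen (0.97 ± 0.18) in the authors' deposited table. Of 25 heat shock protein genes 14 were called higher and 4 lower (adjusted p = 0.00106, Fisher's exact test), although HSP17.9B was lower at -2.34 ± 0.23 in the authors' deposited table. Of 17 genes of the DNA methylation machinery 9 were called higher and 1 lower (median 0.42, adjusted p = 0.0183, Fisher's exact test). Of 10 nitrogen metabolism and hypoxia markers 5 were called lower and 3 higher (adjusted p = 0.0451, Fisher's exact test). HB1 and HB2, nonsymbiotic hemoglobins, were lower at -1.46 ± 0.22 and -1.29 ± 0.17 in the authors' deposited table. SUS1, a sucrose synthase, was lower at -0.90 ± 0.17 and AMY3D at -2.24 ± 0.51 in the authors' deposited table. The glycolysis list, with 3 members higher and 7 lower of 23, did not pass (adjusted p = 0.221 for lower calls, Fisher's exact test). In all, 8806 of 23763 features were called, 5024 higher and 3782 lower, and the share of higher calls was 57.1% as deposited, 44.8% with a normal p and 28.7% with that p on ratios centred on a shift of 0.09. With 2-fold or more it was 38.0%, and the heat shock, embryo maturation and DNA methylation lists did not pass. The heat shock list also did not pass with cameraPR, the DNA methylation list and the markers not with members checked in the reference alone, and the markers not with a background of FPKM of 1 or more.

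At 12 h ethanol fermentation genes and sugar breakdown and glycolysis genes had more higher calls than other genes. Of 7 tested ethanol fermentation genes 6 were called higher and 1 lower (median log2 ratio 1.77, adjusted p = 0.0123, Fisher's exact test; 6 higher when adjusted over the list alone). PDC1, a pyruvate decarboxylase (LOC_Os05g39310, chromosome 5, 23058661 to 23062583, build not given in the sources used here), stood at 112 FPKM in air and 2100 in nitrogen (4.23 ± 0.26) in the authors' deposited table. ADH1, an alcohol dehydrogenase (LOC_Os11g10480, chromosome 11, 5711654 to 5716288), stood at 417 and 720 FPKM (0.79 ± 0.19) in the authors' deposited table. Of 23 sugar breakdown and glycolysis genes 17 were called higher and 1 lower (adjusted p = 5.55e-05, Fisher's exact test). FBA, an aldolase, was higher at 2.45 ± 0.19, and PPDKB, a pyruvate orthophosphate dikinase, was the member called lower at -2.07 ± 0.21 in the authors' deposited table. AMY3D (LOC_Os08g36910, chromosome 8, 23340676 to 23343533), an alpha-amylase of sugar-starved tissue, stood at 5.18 FPKM in air and 283 in nitrogen (5.77 ± 0.21) in the authors' deposited table. The amylase list, with 3 higher and 2 lower of 5, did not pass (adjusted p = 0.327 for higher calls, Fisher's exact test), but passed as higher with cameraPR, as it did at 24 h and 2 d.

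Storage protein, embryo maturation and heat shock protein genes had more higher calls than other genes at 12 h and 24 h. All 11 tested storage protein genes were called higher at both times, with median log2 ratios of 2.17 and 3.13 (adjusted p = 1.17e-05 and 4.21e-05, Fisher's exact test). They were included as markers of endosperm. On the 24 h libraries 12 other endosperm genes, most of them of starch synthesis, had a median of 1.15 beyond the shift. Without the transcription factors among them, RPBF and BZIP58, it lies between 0.52 (SSI) and 0.88 (BEIIB). Embryo maturation genes were called higher in 13 of 15 and 10 of 14 members, or 14 and 11 when adjusted over the list alone (adjusted p = 4.08e-05 and 0.0138, Fisher's exact test), with VP1, a transcription factor of seed maturation, at 1.78 ± 0.22 and 2.06 ± 0.29 in the authors' deposited tables. Heat shock protein genes were called higher in 20 of 25 and 16 of 24 members, or 20 and 17 when adjusted over the list alone (adjusted p = 1.69e-06 and 0.00386, Fisher's exact test). HSP26.7, a small heat shock protein, was higher at 3.10 ± 0.29 and 3.89 ± 0.53 in the authors' deposited tables.

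Cell cycle, photosynthesis, mitochondrial and antioxidant genes had more lower calls than other genes at 12 h and 24 h. Of 17 cell cycle and DNA replication genes 14 were called lower at 12 h and 12 at 24 h, or 15 and 13 when adjusted over the list alone (median log2 ratios -2.65 and -0.50, adjusted p = 1.15e-07 and 1.17e-05, Fisher's exact test). MCM3, a subunit of the replicative helicase, was lower at -3.10 ± 0.21 at 12 h, and CYCB1_1, a mitotic cyclin, at -5.61 ± 0.35 at 24 h in the authors' deposited tables. Photosynthesis genes, included as markers of the primary leaf, were called lower in 17 of 25 and 23 of 26 members, or 17 and 24 when adjusted over the list alone (adjusted p = 2.63e-07 and 6.92e-14, Fisher's exact test). Mitochondrial respiration genes were called lower in 13 of 18 and 11 of 16 members, or 14 and 13 when adjusted over the list alone (adjusted p = 3.07e-06 and 4.08e-05, Fisher's exact test), and antioxidant enzyme genes in 12 of 20 and 12 of 19 (adjusted p = 8.91e-05 and 4.56e-05, Fisher's exact test). Neither of these 2 lists passed with 2-fold or more at either time, and the mitochondrial list did not pass with members checked in the reference alone. APX1, an ascorbate peroxidase, stood at 449 FPKM in air and 182 in nitrogen at 24 h in the authors' deposited table. Expansins, which loosen cell walls, went both ways, with 8 higher and 8 lower of 19 at 12 h and 4 higher and 9 lower of 19 at 24 h; the excess of lower calls passed (adjusted p = 0.0249 and 0.00702, Fisher's exact test), though at 12 h not with cameraPR, with 2-fold or more or with centred calls. EXPB3 was lower at -5.11 ± 0.25 and EXLA1 higher at 3.88 ± 0.36 at 24 h in the authors' deposited table, whereas EXPA7 was not called (-0.02 ± 0.35). HB1 stood at 136 FPKM in air and 1.55 in nitrogen at 24 h in the authors' deposited table. CMT3A, a chromomethylase, was lower at -7.37 ± 0.64 at 12 h in the authors' deposited table, while the DNA methylation list did not pass (5 lower of 19, adjusted p = 0.422, Fisher's exact test) except with cameraPR.

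In all, 11095 of 25521 features were called at 12 h and 12083 of 25319 at 24 h. Higher calls made up 63.4% and 66.9% as deposited, 57.1% and 57.7% with a normal p, and 40.7% and 34.7% with that p on ratios centred on the median shifts of 0.17 and 0.26, and 50.3% and 51.1% with 2-fold or more. Relative to those shifts the fermentation list stood at 1.60 and 1.57, the storage protein list at 2.00 and 2.87 and the photosynthesis list at -1.49 and -2.47.

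**Figure D1:**
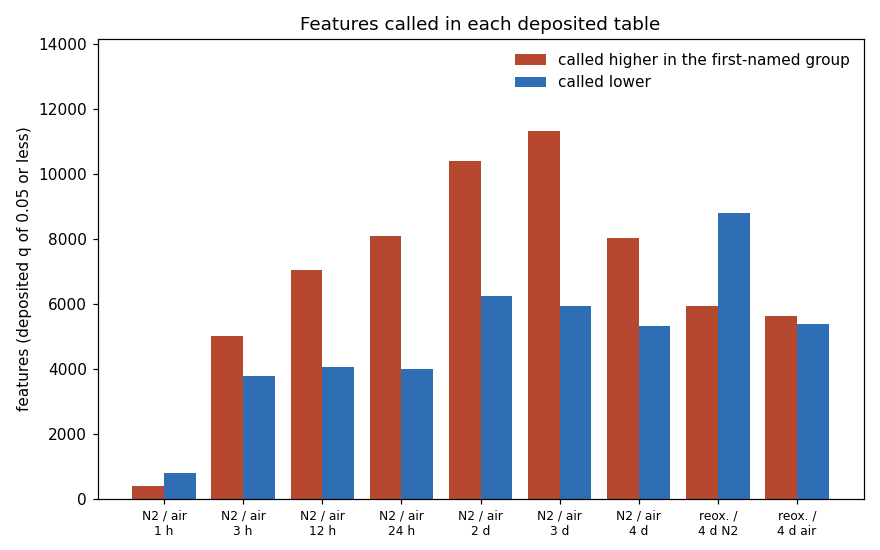
Bars give the number of features called at a deposited q of 0.05 or less in 7 air versus nitrogen tables and 2 reoxygenation tables, split into higher and lower. The fewest calls are at 1 h (1215) and the most at 3 d (17269).

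In coleoptiles at 2 d and at 3 d 6 of 7 fermentation genes were called higher and 1 lower, with medians of 2.00 and 2.33; the excess passed at 2 d (adjusted p = 0.0473, Fisher's exact test) and not at 3 d (adjusted p = 0.148, Fisher's exact test). At 2 d it did not pass with a background of FPKM of 1 or more or with members checked in the reference alone. At 3 d the fermentation list did pass under another setting (adjusted p = 0.00101, Fisher's exact test), though not with cameraPR. That value is the lowest of 6 alternatives, which ran up to an adjusted p of 0.171 (Fisher's exact test or cameraPR). PDC1 stood at 39.3 FPKM in air and 1685 in nitrogen at 2 d (5.42 ± 0.25), and at 12.6 and 1520 at 3 d (6.91 ± 1.40) in the authors' deposited tables. Glycolysis genes were called higher in 18 and 15 of 24 members, or 18 and 16 when adjusted over the list alone (adjusted p = 0.00271 and 0.191, Fisher's exact test). At 3 d this list, too, passed under another setting (adjusted p = 0.00277, Fisher's exact test) and not with cameraPR. Again this is the lowest of 6 alternatives, which ran up to an adjusted p of 0.364 (Fisher's exact test or cameraPR). SUS1 at 3 d stood at 561 and 2632 FPKM without being called (2.23 ± 7.35, q = 0.0542) in the authors' deposited table. All 11 storage protein genes were higher at 2 d (median 4.50, adjusted p = 0.0002, Fisher's exact test), and only 2 were tested at 3 d. Heat shock protein genes were called higher in 16 of 23 members at 2 d (adjusted p = 0.0121, Fisher's exact test) and 8 of 19 at 3 d (adjusted p = 1, Fisher's exact test).

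Photosynthesis genes were called lower in 25 of 27 members at 2 d and 26 of 28 at 3 d (adjusted p = 9.98e-13 and 3.98e-13, Fisher's exact test), with RCA, the activase of Rubisco, at -3.83 ± 0.23 at 3 d in the authors' deposited table. Since this list marks primary leaf, a difference in leaf tissue cannot be told apart from one in expression. Mitochondrial genes were called lower in 14 of 16 and 10 of 18 members (adjusted p = 1.69e-06 and 0.0135, Fisher's exact test). Antioxidant genes were called lower in 14 and 13 of 20 (adjusted p = 8.82e-05 and 0.000551, Fisher's exact test). With 2-fold or more the mitochondrial list did not pass at 3 d, nor did it with checked members alone, and the antioxidant list did not pass at 2 d. CATA, a catalase, stood at 53.9 FPKM in air and 0.15 in nitrogen at 2 d (-8.45 ± 0.70) in the authors' deposited table. Cell cycle genes were called lower in 15 of 17 members at 2 d (adjusted p = 4.99e-07, Fisher's exact test) and 7 of 17 at 3 d (adjusted p = 0.229, Fisher's exact test). At 2 d expansins were called lower in 10 of 19 members (adjusted p = 0.0197, Fisher's exact test), with EXPB2 at -8.16 ± 0.65 in the authors' deposited table; the list did not pass with cameraPR. The locus listed as EXPB12, for which the reference carries no such symbol, was higher at 1.45 ± 0.22 at 2 d and 2.54 ± 0.26 at 3 d in the authors' deposited tables. In all, 16655 of 27564 features were called at 2 d and 17269 of 25989 at 3 d. The share of higher calls was 62.5% and 65.6% as deposited, 57.6% and 62.5% with a normal p, and 39.8% and 40.2% with that p on ratios centred on shifts of 0.25 and 0.39. Features without a locus held 56.3% of the summed FPKM in 3 d air and 41.6% in 3 d nitrogen.

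**Figure D2:**
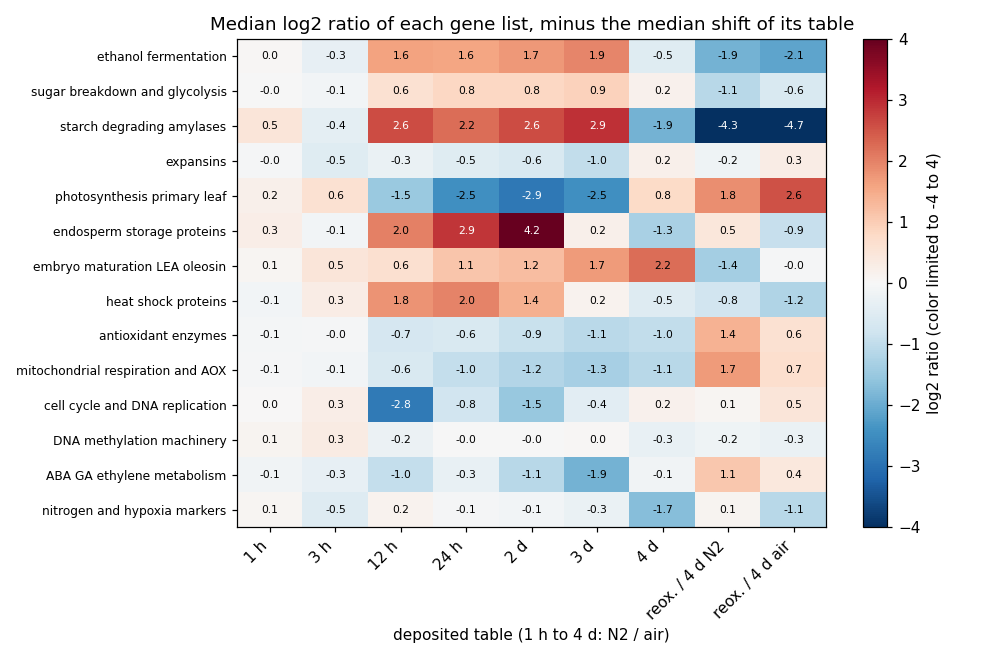
Each cell is the median log2 ratio of a gene list minus the median shift of its table, for 7 air versus nitrogen tables and 2 reoxygenation tables; color is limited to -4 to 4. The storage protein row rises to 4.25 at 2 d and the photosynthesis row turns from -2.45 at 3 d to 0.76 at 4 d.

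At 4 d photosynthesis genes were higher in nitrogen, and the fermentation list did not pass. Of 7 fermentation genes 2 were called higher and 2 lower (median -0.19, adjusted p = 1 for higher calls, Fisher's exact test). ADH1 stood at 654 FPKM in air and 649 in nitrogen (-0.01 ± 0.61, not called), and PDC1 at 277 and 1360 (2.30 ± 0.78) in the authors' deposited table. Of 12 nitrogen metabolism and hypoxia markers 7 were called lower (adjusted p = 0.0249, Fisher's exact test), with HB2 at -2.19 ± 0.34 in the authors' deposited table; this list did not pass with 2-fold or more, with members checked in the reference alone or with centred calls. Photosynthesis genes were called higher in 17 of 26 members and lower in 5 (median 1.04, adjusted p = 0.00647, Fisher's exact test), and CAB1R, a light-harvesting protein, was higher at 2.34 ± 0.32 in the authors' deposited table. The difference of this list between 3 d and 4 d was 3.31, up in 26 of 26 members (p = 1e-05, the smallest these permutations can give, adjusted p = 0.000253, permutation test). For the markers it was -1.37 (adjusted p = 0.0653, permutation test), not past the threshold. For fermentation genes it was -2.69, where the exact sign-flip test of 7 members could not have passed (its smallest p is 0.0156, or 0.0545 adjusted). The labels state that primary leaf tissue was removed from coleoptiles in air at these later times. Mitochondrial genes were called lower in 12 of 18 members and antioxidant genes in 10 of 20 (adjusted p = 0.000409 and 0.021, Fisher's exact test), the antioxidant list not with cameraPR. Neither list passed with 2-fold or more, and with checked members alone neither the photosynthesis nor the mitochondrial list did. AOX1A, an alternative oxidase, was lower at -4.04 ± 0.65 and SODCC2, a superoxide dismutase, at -3.18 ± 0.33 in the authors' deposited table. EXPB11 was higher at 4.98 ± 0.39 and EXPB6 lower at -3.31 ± 0.33 in the authors' deposited table. In all, 13356 of 24685 features were called, 8041 higher and 5315 lower. Higher calls made up 60.2% as deposited, 55.6% with a normal p and 41.9% with that p on ratios centred on a shift of 0.28. The median implied SE was 0.33, against 0.22 at 3 d. It was 0.32 to 0.35 in all comparisons with 4 d air, and 0.23 to 0.24 in those of 4 d nitrogen without 4 d air.

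**Figure D3:**
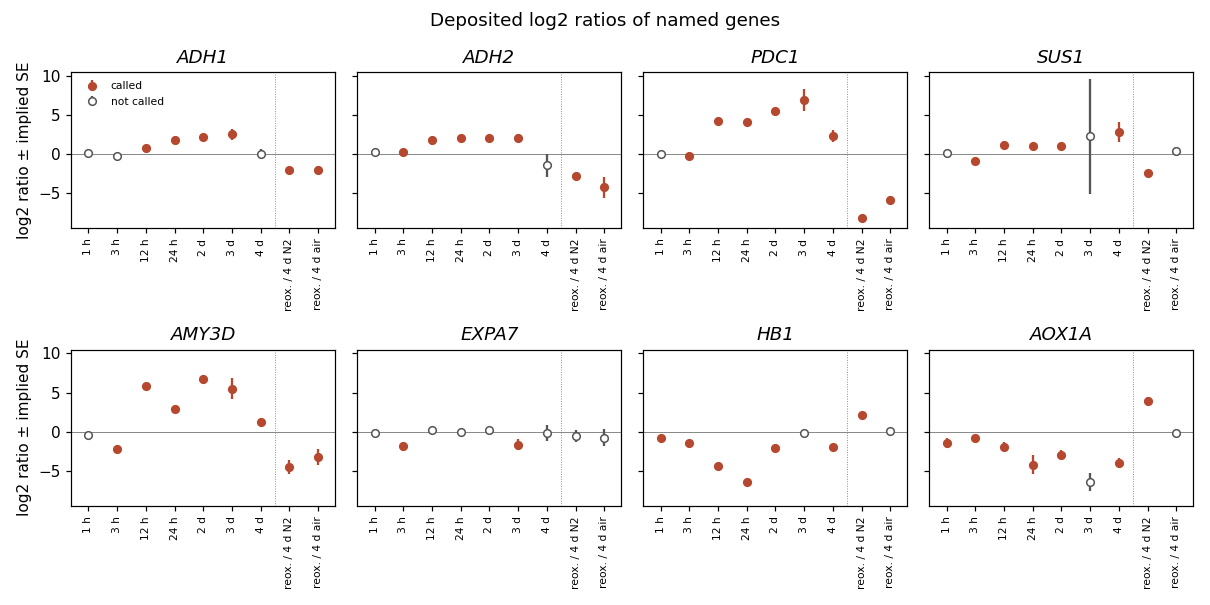
Points give the deposited log2 ratio of 8 genes in 7 air versus nitrogen tables and 2 reoxygenation tables, with bars for the implied SE; filled points were called and open points were not. PDC1 reaches 6.91 at 3 d and -8.18 after return to air.

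Return to air for 1 d after 3 d in nitrogen was set against 4 d in nitrogen. Fermentation genes were called lower in 6 of 7 members (median -2.09, adjusted p = 0.0368, Fisher's exact test), and PDC1 went from 1415 FPKM in nitrogen to 4.87 after reoxygenation (-8.18 ± 0.36) in the authors' deposited table. Glycolysis genes were called lower in 15 of 24 members (adjusted p = 0.0348, Fisher's exact test), with SUS1 at -2.45 ± 0.33 in the authors' deposited table. With members checked in the reference alone neither list passed, and with a background of FPKM of 1 or more the glycolysis list did not. Photosynthesis genes were called higher in 23 of 28 members, mitochondrial genes in 14 of 16 and antioxidant genes in 13 of 20 (adjusted p = 7.66e-09, 3.07e-06 and 0.000916, Fisher's exact test). As the photosynthesis list marks primary leaf, a difference in leaf tissue cannot be told apart from a change in expression. AOX1A was higher at 3.86 ± 0.58 and HB1 at 2.12 ± 0.30 in the authors' deposited table. Among expansins EXPB6 was higher at 4.57 ± 0.22 and the locus listed as EXPB12 lower at -5.25 ± 0.50 in the authors' deposited table, while the list did not pass (8 lower of 18, adjusted p = 0.719, Fisher's exact test). In all, 14737 of 24650 features were called, 5931 higher and 8806 lower. Higher calls made up 40.2% as deposited, 44.1% with a normal p and 56.8% with that p on ratios centred on a shift of -0.21.

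Against 4 d in air, reoxygenated coleoptiles still differed in 11026 of 24405 features, 5624 higher and 5402 lower. Fermentation genes were called lower in 5 of 7 members and nitrogen metabolism and hypoxia markers in 10 of 12 (adjusted p = 0.0297 and 0.00011, Fisher's exact test). Amylases were called lower in 4 of 5 members, glycolysis genes in 11 of 23 (12 when adjusted over the list alone) and heat shock protein genes in 9 of 18 (adjusted p = 0.0366, 0.0344 and 0.0338, Fisher's exact test). None of these 3 lists passed with cameraPR, and the markers did not pass with members checked in the reference alone. The antioxidant list passed for higher calls (adjusted p = 0.0452, Fisher's exact test). The mitochondrial and cell cycle lists passed as well (adjusted p = 0.0138 and 0.0287, Fisher's exact test), in a direction not given here. With cameraPR the antioxidant, mitochondrial and cell cycle lists pointed to higher after reoxygenation, and of them only the antioxidant list passed. With 2-fold or more or with checked members alone none of them did. ADH2 stood at 3269 FPKM in 4 d air and 170 after reoxygenation (-4.26 ± 1.35) in the authors' deposited table. Photosynthesis genes were called higher in 27 of 28 members (adjusted p = 3.22e-14, Fisher's exact test), and CATA was higher at 7.19 ± 0.47 in the authors' deposited table. Primary leaf, which the photosynthesis list marks, was removed from coleoptiles in air at these later times per the labels. A difference in leaf tissue cannot be told apart here from a change in expression. AOX1A (-0.18 ± 0.37) and HB1 (0.12 ± 0.34) were not called in the authors' deposited table.

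The changes on reoxygenation were mostly opposite to those of nitrogen. Of 16588 genes called at 3 d and tested on reoxygenation, 69.7% were called the opposite way and 3.7% the same way, where independent calls would give 32.0% opposite (odds ratio 0.00291 for the same direction). Across 23731 genes Spearman's rho was -0.787; genes are not independent replicates. These tables share no library. The 4 d table, which shares its nitrogen libraries with the reoxygenation table, gave a rho of -0.617 over 22390 genes against a simulated -0.373 with no effect, and a covariance of -2.09 against a simulated -1.50. Among genes called in both, 88.5% went opposite ways, against 97.6% in the simulation. These 2 shares cannot be set against each other, since simulated calls used an unadjusted normal p of 0.05 and not the deposited q. With no effect planted, genes pass in both mainly through the shared libraries, so a high simulated share was set in advance. Part of the rho of -0.617 comes with the shared libraries, which could not be split. The simulation drew normal noise from the implied SEs, which are very large for some genes (17.8 for LOC_Os01g32160 at 4 d, where the median was 0.33). A few such genes can set a covariance, so these values do not give the share that comes from shared libraries. Against 4 d air, 25.9% of the genes called at 3 d were called the opposite way after reoxygenation and 24.8% the same way. Independent calls would give 22.2% opposite there, and rho was -0.047.

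**Figure D4:**
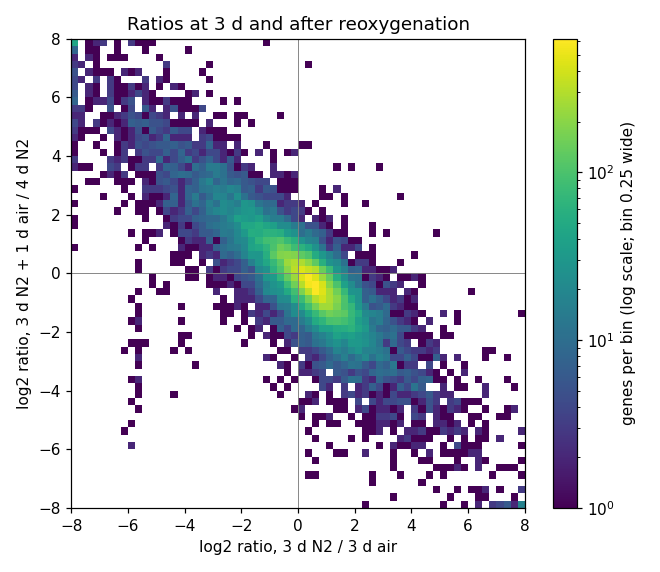
Each bin counts genes by their log2 ratio at 3 d (x axis) and after reoxygenation (y axis), with color on a log scale and ratios beyond 8 drawn at the edge. Over 23731 genes rho is -0.787.

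Calls at successive times were compared in direction. Between 1 h and 3 h 91.8% of 892 genes called at both went the same way, between 3 h and 12 h 50.8% of 4634 (rho -0.016 across genes), and between 12 h and 24 h 97.6% of 8153. Independent calls would give 1433 genes higher and 513 lower at both 3 h and 12 h, and 1688 and 667 were found. These excesses do not show agreement between 3 h and 12 h. The number that independent calls would send opposite ways was not computed beside them. Between 24 h and 2 d the share was 96.7% of 10173, between 2 d and 3 d 89.7% of 12384, and between 3 d and 4 d 90.7% of 10568.

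Within each gas, successive times were compared with one another. From dry seed to 1 h in nitrogen 3252 of 23715 features were called, and all 11 storage protein genes were called higher (median log2 ratio 1.66). The share of higher calls was 41.0% as deposited, 69.0% with a normal p and 80.7% with that p on ratios centred on a shift of -0.08, and 63.9% with 2-fold or more. From dry seed to 24 h in air 18248 of 26515 features were called, with all 15 embryo maturation genes and all 11 storage protein genes lower and 16 of 17 cell cycle genes higher. In nitrogen over the same span 17167 of 25846 features were called. All 15 maturation genes were called lower there as well, whereas of 11 storage protein genes 2 were called higher and 0 lower. Higher calls in air and nitrogen made up 32.8% and 36.4% as deposited, 34.3% and 37.4% with a normal p, and 55.6% and 53.6% with that p on ratios centred on shifts of -0.67 and -0.44. HB1 rose in air by 6.15 ± 0.47 and was not called in nitrogen (-0.28 ± 0.70) in the authors' deposited tables. PDC1 rose 3.54 ± 0.20 from 1 h to 3 h in air and 3.31 ± 0.20 in nitrogen in the authors' deposited tables. From 3 h to 12 h it changed by -2.02 ± 0.24 in air and by 2.48 ± 0.21 in nitrogen in the authors' deposited tables.

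Early steps called 12362 features in air and 5763 in nitrogen from 1 h to 3 h, 17832 and 16820 from 3 h to 12 h, and 7152 and 5774 from 12 h to 24 h. Over these 3 steps in air, higher calls made up 37.5%, 38.2% and 45.5% as deposited, 43.1%, 37.9% and 57.8% with a normal p, and 62.7%, 54.9% and 67.3% with that p on centred ratios. In nitrogen they made up 38.1%, 40.6% and 54.2% as deposited, 68.7%, 40.2% and 52.5% with a normal p, and 84.4%, 53.6% and 52.5% with that p on centred ratios. With 2-fold or more these shares were 54.2%, 38.8% and 59.6% in air and 70.3%, 42.3% and 49.1% in nitrogen. From 24 h to 2 d, where the tissue changes from embryo to coleoptile, 10716 features were called in air and 6013 in nitrogen. At that step higher calls in air and nitrogen made up 44.9% and 44.5% as deposited, 57.3% and 66.6% with a normal p, and 67.7% and 77.3% with that p on ratios centred on shifts of -0.09 and -0.10, and 60.5% and 65.6% with 2-fold or more. From 2 d to 3 d 15493 were called in air and 11167 in nitrogen, and from 3 d to 4 d 11933 and 3336. In air at that last step PDC1 rose 4.43 ± 0.58 and ADH1 2.19 ± 0.81 in the authors' deposited table, and 27 of 28 photosynthesis genes were called lower. Removal of primary leaf from coleoptiles in air, stated in the labels, cannot be told apart there from a change in expression. Set against dry seed, 17468 of 26108 features were called at 4 d in air and 18082 of 25647 in nitrogen, and set against 24 h 14001 and 13743 were.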

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

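The tests of the authors' normalization at 4 d (all 3) and at 24 h, of slower loss of stored transcripts and of swapped labels at 3 h (both) were chosen after the result was seen. Of 76 differences of a gene list between successive times, 17 had an adjusted p of 0.05 or less in the sign-flip test, all on ratios relative to the median shift; the members of a list are not independent replicates. With the other tests as they were, 7 of the 76 could not have passed because of too few members: the 6 of fermentation genes and that of embryo maturation genes from 3 d to 4 d.

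From 1 h to 3 h the mean ratio of nitrogen over air moved by 0.50 for photosynthesis genes, -0.33 for storage protein genes and 0.35 for embryo maturation genes. From 3 h to 12 h it moved by 0.78 for glycolysis genes, -1.98 for photosynthesis genes, 2.06 for storage protein genes, 1.08 for heat shock protein genes and -2.29 for cell cycle genes. From 12 h to 24 h it moved by -0.97 for expansins, -0.996 for photosynthesis genes and 1.08 for storage protein genes. From 24 h to 2 d it moved by 1.21 for storage protein genes and -0.60 for antioxidant genes. From 2 d to 3 d it moved by 0.51 for embryo maturation genes and 1.46 for cell cycle genes. From 3 d to 4 d it moved by 3.31 for photosynthesis genes, up in 26 of 26 members, and by 1.22 for abscisic acid, gibberellin and ethylene genes.

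Fermentation, glycolysis and hypoxia marker genes were called higher in nitrogen in 27 members at 3 d and 13 at 4 d. The median implied SE was 0.22 at 3 d and 0.33 at 4 d, and a larger SE by itself lowers the number of calls. As differences between the times, glycolysis (adjusted p = 0.135, permutation test) and the markers (adjusted p = 0.0653, permutation test) did not pass. Fermentation could not have passed with 7 members (smallest adjusted p 0.0545). Nitrogen libraries among the 4 d air libraries are argued against: 70.5% of 61 genes that were 16-fold or more higher in nitrogen at 2 d and 3 d lay under 20% of their nitrogen level in 4 d air, where a wrong library would allow at most 5%. The normalization of the 4 d air libraries was tested as the whole cause, since 1 factor moves all genes alike. By their medians from 3 d to 4 d in air all 3 lists stood at percentile 99.99 or above among 10000 random lists matched on FPKM. The 3 lists had been picked by a pattern in the same 3 d and 4 d air libraries, so high percentiles were partly to be expected. These lists rose more than other genes, which 1 factor alone does not give, but the test is not independent of how they were picked. That test was added after 2 others had not decided: the 18 members with a median of 1.502 beyond the shift were picked by their calls, and over all 42 tested members the median was 1.20, with an interval of 0.43 to 1.52 that reaches below the bound of 0.5 set for it. A state of the 4 d air coleoptiles nearer to that in nitrogen remains open as a hypothesis. Across genes the change from 3 d to 4 d in air correlated with the nitrogen ratio at 2 d at rho 0.341, and what might have brought it about was not tested. The labels state that primary leaf tissue was removed from coleoptiles in air at these later times. Photosynthesis genes, the markers of that leaf, were mostly lower both from 3 d to 4 d in air and in nitrogen at 2 d. Leaf removal would push rho the same way, and it cannot be told apart from a nitrogen-like state here.

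Storage protein transcripts were higher in nitrogen at 12 h, 24 h and 2 d. The normalization of the 24 h libraries is argued against, as their median lay 2.87 beyond the shift. Slower loss of all stored transcripts by the same log2 amount is argued against. The embryo maturation list lay 1.75 lower than the storage list (-1.75 as a difference), with interquartile ranges of 1.13 to 1.76 and 3.01 to 3.23. A slower loss that differs in size between transcripts cannot be excluded this way, since it could also give unequal medians. More endosperm left on the nitrogen samples stays open: 12 tested endosperm genes, most of them of starch synthesis, had a median 1.15 beyond the shift. They include the transcription factors RPBF and BZIP58, at 1.42 and 3.68 beyond the shift. Both lie above that median. Without them the median lies between SSI (0.52 beyond the shift) and BEIIB (0.88), under the bound set beforehand for more endosperm. Reaching that bound therefore rests on these transcription factors, and the set does not decide. BZIP58 and BT1-1 were not called and stood at 0.07 and 0.09 FPKM in air. The interval of the median of all 12 genes is wide (0.39 to 2.75). The levels in air and nitrogen were unequal (AGPS2 45.7 and 58.2 FPKM, BEI 12.3 and 17.8, SSI 11.8 and 20.3, ISA1 11.3 and 12.0, WX 1.40 and 22.6). A slower loss of endosperm transcripts alone therefore also stays open, untested.

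Differences at 3 h were unlike those from 12 h on. Swapped labels at 3 h alone are argued against. Of 244 genes called the same way at 1 h and 12 h and called at 3 h, 90.6% went that way at 3 h. The interval was 86.3 to 93.6. A swap at 3 h alone would allow at most 20%, if the 1 h labels are right. The value mostly restates the agreement between 1 h and 3 h (91.8% of 892 genes). Labels swapped at both 1 h and 3 h would give it too, so that is not excluded. Between the 3 h and 12 h ratios rho, -0.016, would lie near 0 with the labels either way. The normalization at 3 h is argued against, since 50.9% of 938 genes called at both times with a normal p on centred ratios went the same way. Whether germination was less advanced in nitrogen at 3 h cannot be told apart from other biology: rho of the 3 h ratio with the change from dry seed to 24 h in air was -0.284, between the bounds of -0.3 and -0.1 set before the value was seen.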

How the results depend on the processing

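The settings with a normal p and no centring, without features lacking a locus, with members checked in the reference alone, without the 4 d air tables and with calls from centred ratios for lists, reversal and direction were chosen after seeing the data. No paired analysis was possible because the deposited tables hold group means and no values per library, and for the same reason no replicate could be left out and no other split of the samples could be counted. Lists by product description were not run, since the reference gives no products. Depth is unknown, so its limit on any value could not be given.

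Among counts of called features under other settings 132 stayed within 1.5 times the count as reported and 92 did not. An FPKM minimum of 1 and leaving out features without a locus kept all 28 counts within that range. The second setting drops the calls of those features alone and keeps the deposited q and FPKM. With 3259 of 24187 tested features at 1 h, they were too few to move a count far. Where a setting asks for a larger change or a smaller q, fewer features pass by its construction; calls from centred ratios change both the centre and the p, and the counts with a normal p alone are given to part these; why a normal p gives fewer calls was not tested.

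With a change of 2-fold or more the number of called features was 178 (1 h), 1591 (3 h), 3854 (12 h), 4754 (24 h), 7996 (2 d), 9202 (3 d), 8894 (4 d) for nitrogen over air. For the others it was 7773 (reoxygenated over 4 d nitrogen), 6439 (reoxygenated over 4 d air), 842 (1 h nitrogen over dry seed), 3052 (3 h air over 1 h air), 10845 (12 h air over 3 h air), 2492 (24 h air over 12 h air), 3745 (2 d air over 24 h air). Then it was 7269 (3 d air over 2 d air), 6778 (4 d air over 3 d air), 1321 (3 h nitrogen over 1 h nitrogen), 9980 (12 h nitrogen over 3 h nitrogen), 1743 (24 h nitrogen over 12 h nitrogen), 1758 (2 d nitrogen over 24 h nitrogen), 4474 (3 d nitrogen over 2 d nitrogen). Then it was 737 (4 d nitrogen over 3 d nitrogen), 6514 (4 d nitrogen over 24 h nitrogen).

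With 2-fold on FPKM + 1 it was 68 (1 h), 748 (3 h), 2535 (12 h), 3189 (24 h), 4893 (2 d), 6014 (3 d), 6819 (4 d) for nitrogen over air. For the others it was 5565 (reoxygenated over 4 d nitrogen), 4744 (reoxygenated over 4 d air), 370 (1 h nitrogen over dry seed), 10890 (24 h air over dry seed), 9033 (24 h nitrogen over dry seed), 11536 (4 d air over dry seed), 10743 (4 d nitrogen over dry seed). Then it was 1589 (3 h air over 1 h air), 8107 (12 h air over 3 h air), 1572 (24 h air over 12 h air), 2054 (2 d air over 24 h air), 4629 (3 d air over 2 d air), 4586 (4 d air over 3 d air), 7323 (4 d air over 24 h air). Then it was 630 (3 h nitrogen over 1 h nitrogen), 7274 (12 h nitrogen over 3 h nitrogen), 939 (24 h nitrogen over 12 h nitrogen), 846 (2 d nitrogen over 24 h nitrogen), 2478 (3 d nitrogen over 2 d nitrogen), 330 (4 d nitrogen over 3 d nitrogen), 4296 (4 d nitrogen over 24 h nitrogen).

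With centred ratios it was 319 (1 h), 2591 (3 h), 5100 (12 h), 5279 (24 h), 10168 (2 d), 11193 (3 d), 8534 (4 d) for nitrogen over air. For the others it was 6211 (reoxygenated over 4 d air), 636 (1 h nitrogen over dry seed), 5748 (3 h air over 1 h air), 2701 (24 h air over 12 h air), 4548 (2 d air over 24 h air), 6645 (4 d air over 3 d air), 1528 (3 h nitrogen over 1 h nitrogen). Then it was 1968 (24 h nitrogen over 12 h nitrogen), 1588 (2 d nitrogen over 24 h nitrogen), 5843 (3 d nitrogen over 2 d nitrogen), 745 (4 d nitrogen over 3 d nitrogen), 8684 (4 d nitrogen over 24 h nitrogen).

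With a normal p and no centring it was 263 (1 h), 2700 (3 h), 5529 (12 h), 6082 (24 h) for nitrogen over air. For the others it was 6197 (reoxygenated over 4 d air), 626 (1 h nitrogen over dry seed), 6493 (3 h air over 1 h air), 2654 (24 h air over 12 h air), 4640 (2 d air over 24 h air), 6689 (4 d air over 3 d air), 9330 (4 d air over 24 h air). Then it was 1557 (3 h nitrogen over 1 h nitrogen), 1968 (24 h nitrogen over 12 h nitrogen), 1537 (2 d nitrogen over 24 h nitrogen), 5955 (3 d nitrogen over 2 d nitrogen), 734 (4 d nitrogen over 3 d nitrogen), 8764 (4 d nitrogen over 24 h nitrogen).

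At a q of 0.01 or less it was 765 (1 h) for nitrogen over air. For the others it was 1865 (1 h nitrogen over dry seed), 3833 (2 d nitrogen over 24 h nitrogen), 2160 (4 d nitrogen over 3 d nitrogen). Adjusted over all tables it was 2621 (1 h) for nitrogen over air. With 2-fold or more the share of higher calls in nitrogen over air was 5.6% (1 h), 38.0% (3 h), 50.3% (12 h), 51.1% (24 h), 53.4% (2 d), 58.0% (3 d) and 56.7% (4 d).

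Of genes called 2-fold or more at both times, the percentage going the same way moved out of its 95% interval to 97.2 (1 h and 3 h), 50.7 (1 h and 12 h), 43.8 (1 h and 24 h), 63.5 (1 h and 3 d), 77.6 (1 h and 4 d), 53.0 (3 h and 12 h), 49.2 (3 h and 2 d). Later pairs gave 51.0 (3 h and 3 d), 58.8 (3 h and 4 d), 98.7 (12 h and 24 h), 96.1 (12 h and 2 d), 87.8 (12 h and 3 d), 71.0 (12 h and 4 d). Remaining pairs gave 97.5 (24 h and 2 d), 93.1 (24 h and 3 d), 79.3 (24 h and 4 d), 96.0 (2 d and 3 d), 83.1 (2 d and 4 d), 95.8 (3 d and 4 d). With centred calls that percentage was 97.2 (1 h and 3 h), 51.3 (1 h and 12 h), 53.3 (1 h and 24 h), 54.9 (1 h and 2 d), 73.6 (1 h and 3 d), 82.9 (1 h and 4 d), 59.6 (3 h and 24 h). Later pairs gave 48.9 (3 h and 2 d), 64.1 (3 h and 4 d), 98.8 (12 h and 24 h), 96.1 (12 h and 2 d), 88.4 (12 h and 3 d), 69.8 (12 h and 4 d). Remaining pairs gave 97.6 (24 h and 2 d), 93.1 (24 h and 3 d), 77.1 (24 h and 4 d), 94.7 (2 d and 3 d), 78.6 (2 d and 4 d), 93.6 (3 d and 4 d).

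The share of genes reversed on reoxygenation, 69.7%, was 62.7% with 2-fold or more in both tables, 62.8% with the 2 d calls, 70.8% with an FPKM minimum of 1 and 68.6% with centred calls. Among counts of gene lists past the threshold 46 stayed within that factor and 6 did not. At 1 h the count went to 1 with 2-fold or more and to 1 with centred calls. At 3 h it went to 2 with checked members alone, which are fewer. At 4 d it went to 1 with 2-fold or more and to 1 with checked members, and for reoxygenated coleoptiles over 4 d air to 3 with checked members; apart from fewer members or calls the cause was not tested. With cameraPR 10 lists no longer passed. These were heat shock at 1 h (adjusted p = 0.065, over all alternatives from 0.0241 to 1) and 3 h (0.0783, from 0.000902 to 0.867), expansins at 12 h (0.354, from 0.022 to 0.354) and 2 d (0.0689, from 0.0122 to 0.0689), and antioxidant enzymes at 4 d (0.0783, from 0.0127 to 0.0992). For reoxygenated coleoptiles over 4 d air they were glycolysis (0.361, from 0.0277 to 0.412), amylases (0.0783, from 0.000216 to 0.132), heat shock (0.256, from 0.0242 to 0.813), mitochondrial genes (0.0558, from 0.0214 to 1) and cell cycle genes (0.0861, from 0.0408 to 1). With cameraPR 12 lists passed that had not. As higher these were amylases at 12 h (adjusted p = 1.67e-15, over all alternatives up to 0.366), 24 h (1.88e-05, up to 0.577) and 2 d (5.5e-06, up to 0.368), DNA methylation at 1 h (0.0109, up to 1), photosynthesis at 3 h (0.013, from 0.00784 to 0.622) and expansins at 4 d (0.0195, from 0.00688 to 0.736). As lower they were DNA methylation at 12 h (0.0442, up to 0.769) and the hormone genes at 3 h (0.0359, from 0.00986 to 0.854) and 12 h (0.0497, from 0.0195 to 0.723). On reoxygenation they were embryo maturation as lower than 4 d nitrogen (0.0403, up to 0.716), and expansins (0.00758, from 0.00623 to 0.171) and hormone genes (0.000282, up to 0.364) as higher than 4 d air. Asking for 2-fold or more ended 18 list results: storage proteins at 1 h, heat shock at 1 h and 3 h, embryo maturation and DNA methylation at 3 h, expansins at 12 h, antioxidant enzymes at 12 h, 24 h, 2 d and 4 d, mitochondrial genes at 12 h, 24 h, 3 d and 4 d, the hypoxia markers at 4 d, and antioxidant, mitochondrial and cell cycle genes for reoxygenated coleoptiles over 4 d air. Checked members alone ended 19: DNA methylation at 3 h, the hypoxia markers at 3 h and 4 d, mitochondrial genes at 12 h, 24 h, 3 d and 4 d, fermentation at 24 h and 2 d, the hormone genes at 2 d, photosynthesis at 4 d, fermentation and glycolysis for reoxygenated coleoptiles over 4 d nitrogen, and glycolysis, amylases, antioxidant, mitochondrial and cell cycle genes and the markers for reoxygenated coleoptiles over 4 d air. A background of FPKM of 1 or more ended 7: heat shock at 1 h, the hypoxia markers at 3 h, fermentation at 2 d, glycolysis over 4 d nitrogen, and amylases, heat shock and antioxidant enzymes over 4 d air. Centred calls ended 7: storage proteins and heat shock at 1 h, expansins at 12 h, the hypoxia markers at 4 d, and glycolysis, heat shock and cell cycle genes over 4 d air. For the hypoxia markers at 4 d the adjusted p was 0.101 with 2-fold or more, 0.224 with checked members and 0.0714 with centred calls, over all alternatives from 0.0146 to 0.224. Of the separate list results 630 kept their side of the threshold, 37 passed that had not, 61 no longer passed and 0 reversed. Of the 37, 12 came with cameraPR, 12 with 2-fold or more, 11 with centred calls and 2 with a background of FPKM of 1 or more. Those gained without cameraPR include fermentation and glycolysis at 3 d. Among values of named genes 6385 kept their side, 711 no longer passed, 11 passed that had not and 1 reversed. The last was GLUB4, a glutelin, from 3 h to 12 h in nitrogen, called at -0.26 in the authors' deposited table and at 0.0342 relative to the median shift of -0.29, so that subtracting the shift turns its sign.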

Other observations

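Genes of abscisic acid, gibberellin and ethylene metabolism were called lower in nitrogen in 12 of 20 members at 2 d and 12 of 19 at 3 d (median log2 ratios -0.86 and -1.52, adjusted p = 0.00243 and 0.00141, Fisher's exact test); at 2 d the list did not pass with members checked in the reference alone. After return to air 12 of 19 were called higher than in 4 d nitrogen (adjusted p = 0.0023, Fisher's exact test). At 24 h ACO1, an enzyme of ethylene synthesis, stood at 12.2 FPKM in air and 1.24 in nitrogen (-3.30 ± 0.42) in the authors' deposited table. RDR2, an RNA-dependent RNA polymerase of the DNA methylation list, was called higher in nitrogen from 12 h to 4 d, with log2 ratios of 1.54, 1.79, 1.96, 2.15 and 0.60 in the authors' deposited tables, and lower after return to air at -2.09 ± 0.24.

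Of tested features without a locus 2.7% were called higher and 2.0% lower in nitrogen at 1 h, 15.9% and 9.8% at 3 h, 20.8% and 7.7% at 12 h, 23.1% and 6.4% at 24 h, 42.7% and 6.7% at 2 d, 36.2% and 11.9% at 3 d, and 25.1% and 13.6% at 4 d. Of features with a locus it was 1.5% and 3.6%, 21.9% and 16.8%, 28.5% and 17.0%, 33.1% and 17.1%, 37.1% and 24.8%, 44.6% and 24.3%, and 33.6% and 22.6% at the same times; these shares were not tested against each other. The locus LOC_Os02g18650, an extreme of its tables by the rule for named genes, stood at 0.604 FPKM in air and 743 in nitrogen at 3 d in the authors' deposited table, and at 522 in 4 d nitrogen and 0.102 after return to air in another table, normalized separately.

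A streak in the plot of 3 d ratios against those after reoxygenation led to 42 features without a locus, chosen after their values were seen: called at 3 d, 32-fold or more lower in nitrogen and at 20 FPKM or more in air. They held 18.6% of the summed FPKM of 3 d air, by which they were picked, and 16.1% of that of 4 d air. In the other 14 groups they held at most 0.42% (2 d nitrogen), with 0.0918% in 2 d air and 0.0376% in reoxygenated coleoptiles. Their median log2 ratio was 8.53 from 2 d to 3 d in air in the authors' deposited table. The tables do not say what these features are, and whether their level comes from the tissue or from the libraries of these groups was not tested. Counts of calls without features lacking a locus stayed within 1.5 times those with them in all 28 tables, and the gene lists hold named loci alone. Those counts kept the authors' q and FPKM. They therefore do not show what the 42 features did to the normalization of other genes.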
